A study of Mus musculus
Mus musculus castaneus with 16 samples.

How the data were processed

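RNA sequencing of total RNA was analysed from TST cells, a hybrid mouse embryonic stem (ES) cell line with 1 X chromosome from Mus musculus (mus), 1 from Mus musculus castaneus (cas) and 1 mutated copy of Tsix. The libraries were 16, with 2 from each of Days 0, 1, 2, 3, 4, 6, 8 and 10 of differentiation by withdrawal of leukaemia inhibitory factor (LIF). Per the labels, RNA was extracted with TRIZOL and libraries were made with a directional kit. The submitters' processing notes credit read trimming to Trim Galore, alignment to the mm10 genome to STAR 2.7.10a and read counting to featureCounts 1.5.0-p1, and the notes give no strand setting for the counting.

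The deposited gene table holds raw counts for 24421 genes, in 3 columns per library (reads assigned to mus, reads assigned to cas, and all reads). The deposited tables of transposable elements (TE) hold counts of mus and cas reads per TE subfamily and chromosome, 1 table for each day. The deposited position files list each allele-assigned TE read with its coordinates on the genome of its own allele. The TE tables were checked against a recount of the position files: all 109814 of their values were equal to the recount. The tables left out values under 5 reads and all 1667 values at which mus and cas had equal counts, and held 98.9% of the reads. A TE subfamily listed at 0 in a table can thus have reads in the position files, which were used for such subfamilies. Embryo libraries of another series, in 392 files, were not used here.

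Gene reads per library numbered 16286234 to 22614563, of which 33.3 to 36.6% were assigned to an allele. TE reads in the tables numbered 797672 to 1241122 per library. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Gene positions were taken from the RefSeq annotation of the GRCm38.p6 assembly, in which 23204 of the symbols (95.0%) were found.

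Expression was compared with edgeR 4.0.16 (R 4.3.3) on all 16 libraries in 1 fit with 8 day groups, by the quasi-likelihood test with TMM normalisation and the edgeR filter on low counts, and a change was called at a Benjamini-Hochberg adjusted p under 0.05. TE counts were summed over chromosomes and both alleles and tested in the same way with their own library sizes. Levels are given as CPM, the read count scaled to the library size in gene reads, or in TE reads for TE. Allelic change was tested with edgeR on mus and cas counts with the library as a block, for X-linked genes and TE subfamilies with at least 10 allelic reads on average, and it is given as the log2 change of the mus to cas ratio. The mus share of a library was the percent of mus reads among mus and cas reads, with Xist left out of the gene share. Chromosome 13 served as the autosomal background, because it was heterozygous in all of its 10 Mb windows, and this choice was made after the shares had been seen. Trends with day were tested by Pearson and Spearman correlation over the 16 libraries, two-sided, with 100000 permutations, in a family of 19 trends. The permutations treated the 16 libraries as independent. Variation that the 2 libraries of a day share can therefore make these p-values too small. The smallest p that these permutations can give is 1e-05. Outside the allelic tests, the p-values measure the spread between libraries. That spread may be technical in part, since the labels do not say whether the libraries of a day came from separate cultures. The p-values of the allelic tests rest on a spread pooled over all genes, or all TE subfamilies, with enough allelic reads. They do not measure how the ratio of a single gene or subfamily varied between libraries, and very small ones should be read with this limit.

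Before the data were examined, 27 gene lists and 12 lists of TE subfamilies were fixed, and 26 and 10 of them had members that could be tested. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation, and p-values were adjusted over the lists of 1 kind and day. The rule for naming genes was also fixed before the data were examined. It took the 10 highest and 10 lowest fold changes at Day 10, and the 4 highest and 4 lowest at Days 2 and 4, among genes past the threshold with a mean of at least 10 CPM on either day and both libraries of the later day outside the range of Day 0. For TE at Day 10 it took the 6 highest and 6 lowest. For mus shares at Day 10 it took the 6 lowest and 6 highest X-linked genes and the 4 lowest and 4 highest TE subfamilies among those with at least 200 allelic reads on average, with all members of a list of reported escape genes. Of each list, the members with the highest mean expression were used as examples, and Xist and Tsix were always given. Where the Day 0 or later libraries had no reads of a gene, a floor of 3 counts per library gave a lower bound of the fold, and with 1 to 3 counts the ratio is given with its 95% counting interval.

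The tests on counts were run on simulated data made from the tables, while list tests, trends and the naming rule were not simulated. At 2-fold the tests recovered 91.3% of changed genes, 94.6% of changed TE subfamilies, 97.6% of X-linked genes with a changed mus share and 70.0% of such X-linked TE subfamilies, and of the calls 3.57 to 6.32% were false. For expression, the simulation used 1 fixed spread between libraries for all rows. For mus shares, it drew both alleles of every unchanged row equally and gave the share no spread between libraries beyond counting. The rates for mus shares therefore cannot show how the tests do where the share itself varies between libraries. In both cases the simulation was simpler than the data. It changed a smaller part of the rows than was called at Day 10, chosen among rows with more reads. These rates hold for that setting and need not carry over to the data. Alternatives were other normalisations, filters and tools (DESeq2 1.42.0), a 2-fold minimum, a replicate block, shares as the median of items, shares without the most abundant items, and each library left out in turn. Added after the data had been seen were TE counts from the position files, the same with identical coordinates counted once, and shares without genes of biased Day 0 share or without the escape list. A planned map of TE by position on the X was not made, because the coordinates of the mus and cas reads lie on different genomes, and gene windows were used. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.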

Results

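Total RNA was sequenced from differentiating TST cells, in which the mus X chromosome is the one that becomes silenced. Day 0 cells were in 2i medium, which holds ES cells in a naive state, and the other cells were taken on Days 1, 2, 3, 4, 6, 8 and 10 after the change to a medium without LIF. There were 2 libraries per day and 16 in all. A library held 16286234 to 22614563 gene reads, with 138641 to 249132 allele-assigned reads in X-linked genes. It held 797672 to 1241122 allele-assigned reads in TE, with 21295 to 51958 of them on the X. Levels are means ± SD of the 2 libraries of a day, and log2 changes from Day 0 are given ± SE from the fit over all libraries, unless another source is stated.

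The first question was how the balance of the X chromosomes changed in X-linked genes as the cells differentiated. X-linked genes drew 49.3% ± 0.0181 (SD, n = 2) of their allelic reads from the mus X at Day 0, 39.8% ± 0.394 at Day 2, 18.7% ± 0.0905 at Day 4 and 5.63% ± 0.301 at Day 10. Genes of chromosome 13, the autosomal background, drew 50.3% ± 0.519 from the mus allele at Day 0 and 50.7% ± 0.108 at Day 10. Xist, the RNA that coats and silences the X, rose from 23.7 ± 2.65 CPM at Day 0 to 169 ± 21.1 at Day 2 (log2 change 2.84 ± 0.30, adjusted p = 2.67e-05) and 345 ± 113 at Day 10 (3.87 ± 0.31, adjusted p = 1.54e-06). Of the allelic reads of Xist (chromosome X, 103460373 to 103483233), 99.2% ± 0.495 were mus at Day 0 and 98.7% ± 0.132 at Day 10. Tsix, its antisense repressor, fell from 68.0 ± 0.537 to 2.00 ± 0.485 CPM (log2 change -5.08 ± 0.14, adjusted p = 2.17e-15). Xist and Tsix overlap on opposite strands and the strand setting of the counting is not given, so their levels are uncertain to the extent that reads of one were counted for the other. The mus share of Tsix was 17.8% ± 0.541 at Day 0, and at Day 10 it had 1 mus and 17 cas reads. The Day 0 shares argue against many Tsix reads, which were mostly cas, in the Xist count at Day 0. Xist reads counted for Tsix are not excluded by them.

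The mus share of X-linked genes fell with day (r = -0.948, rho = -0.994, n = 16, permutation p = 1e-05 for both, the smallest that the permutations can give, adjusted p = 2.71e-05). Without the 2 libraries of Day 10, those farthest from the median day, r was -0.969. Of 439 X-linked genes tested, the mus to cas ratio was lower than at Day 0 in 15 at Day 1, 110 at Day 2, 280 at Day 3, 351 at Day 4 and 366 at Day 10. It was higher in 5 genes at Day 1, 1 at Day 2, 0 at Day 3 and 1 at Day 4. It was higher in 1 gene at Day 10, Cxx1a, named after its values were seen, at 47.6% ± 18.6 and 74.2% (log2 change 1.67, adjusted p = 0.00468), and in 0 genes without Day 0 replicate 1. The median of 275 X-linked genes with at least 20 allelic reads in every library was 48.1% at Day 0, 13.6% at Day 4 and 2.53% at Day 10.

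**Figure D1:**
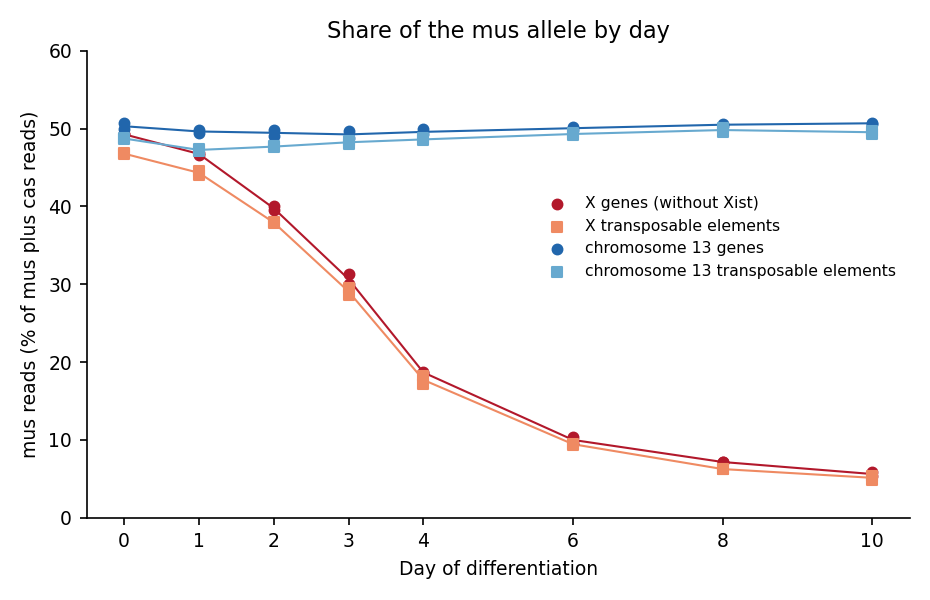
Percent of allelic reads from the mus allele (vertical axis) by day of differentiation (horizontal axis) for X-linked genes, X-linked TE and the genes and TE of chromosome 13, with 1 point per library and lines through the means of 2 libraries. X-linked genes went from 49.3% to 5.63% and X-linked TE from 46.8% to 5.14%, while chromosome 13 genes were at 50.3% and 50.7%.

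Among the 184 X-linked genes with at least 200 allelic reads on average, 129 had a mus share under 5% at Day 10 and 27 a share of at least 10%. The lowest shares were those of Phka1, a subunit of phosphorylase kinase, at 0.251% ± 0.355 (chromosome X, 102513975 to 102644301), and Prdx4, a peroxiredoxin, at 0.311% ± 0.439 (155323918 to 155342272). Armcx1, an armadillo-repeat protein, was at 0.325% ± 0.459 (134717913 to 134721917). At Day 10 Phka1, Prdx4 and Armcx1 had 1, 2 and 2 mus reads, each time in 1 library only, so their order is uncertain. In 182 autosomal windows with almost only mus reads, the median gene had 98.67 to 99.9% mus reads. Some reads may thus be assigned to the wrong allele, and the lowest Day 10 shares of genes, windows and TE may include such reads. The rate at which cas reads were assigned to mus was not measured. Without Day 10 replicate 1 the log2 change of the ratio was -6.72 for Phka1 and -6.56 for Armcx1, against -7.49 and -7.37 with all libraries. Armcx2, Pja1 and Bhlhb9 followed at 0.607% ± 0.0954, 0.650% ± 0.290 and 0.714% ± 0.337. The ratio of Prdx4 fell by 8.89 ± 0.43 on the log2 scale (adjusted p = 3.13e-94, and by 8.02 without Day 10 replicate 2, with no mus read left at Day 10 without replicate 1), and that of Pja1, a ubiquitin ligase gene, by 7.13 ± 0.41 (adjusted p = 2.91e-66). At the other end, after Xist, were Bex4 at 98.2% ± 1.42 and Ngfrap1 at 95.0% ± 0.666. Slc25a5, a mitochondrial ADP/ATP carrier, was at 84.4% ± 1.11, Morf4l2, a chromatin protein, at 82.1% ± 1.58 and Mcf2 at 36.5% ± 11.2. Mcf2, a guanine nucleotide exchange factor, had only 23 allelic reads at Day 10, and the other 4 already had shares of 98.5%, 97.6%, 84.2% and 87.0% at Day 0. The ratio of Morf4l2 was lower at Day 10 than at Day 0 (log2 change -0.55 ± 0.16, adjusted p = 7.02e-04), and those of Bex4 and Slc25a5 were not called (adjusted p = 0.874 and 0.994). Bex4, Slc25a5 and Morf4l2 have related copies in the genome, so the allele assignment of their reads is uncertain. Ngfrap1 had a like bias at Day 0, so the assignment of its reads is uncertain as well. For Ngfrap1 the change of the ratio passed the test narrowly (log2 change -1.10 ± 0.54, adjusted p = 0.0483, and -1.76 without Day 0 replicate 2), and it did not pass without Day 0 replicate 1 (-0.65, adjusted p = 0.332), Day 10 replicate 1 (-0.94, 0.212) or Day 10 replicate 2 (-1.22, 0.0608).

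Genes reported to escape X inactivation in mouse included many of the genes with a high mus share at Day 10. Of the list's 22 members tested for allelic change, 19 had a lower ratio at Day 10 than at Day 0, and 12 still had a mus share of at least 10%, Xist among them. Ogt, which adds sugar groups to nuclear proteins, was at 22.3% ± 0.537, and Kdm6a, a histone demethylase, at 20.6% ± 2.27. Eif2s3x, a translation initiation factor, was at 20.1% ± 0.949, Kdm5c, another histone demethylase, at 17.0% ± 0.916 and Ddx3x, an RNA helicase, at 14.3% ± 0.00715. Pbdc1, Utp14a and Ftx, a noncoding RNA beside Xist, were at 17.5% ± 6.51, 16.8% ± 2.58 and 15.5% ± 1.76. Kdm6a was at 49.2% ± 1.49 at Day 0 and 42.5% ± 1.60 at Day 4, when the change of its ratio did not pass the test (log2 change -0.40 ± 0.21, adjusted p = 0.0652). Other list members were low, with Usp9x at 4.94% ± 1.21, Med14 at 3.86% ± 0.111 and Huwe1 at 2.69% ± 0.196. Car5b had 0 of 90 allelic reads from the mus X, which allows a share of up to 3.33%. The median share was 14.9% for the 16 list members and 2.64% for the 168 other genes with at least 200 allelic reads on average. This difference was not tested.

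**Figure D2:**
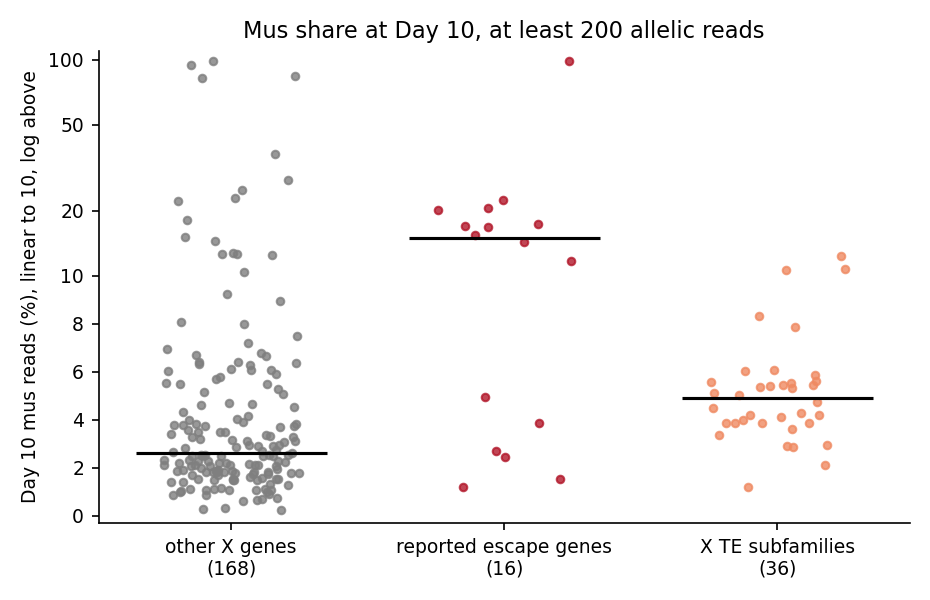
Mus share at Day 10 (percent, axis linear up to 10% and logarithmic above) of X-linked genes, reported escape genes and X-linked TE subfamilies with at least 200 allelic reads on average, with 1 point (mean of 2 libraries) per gene or subfamily and a bar at the median of each set. The medians were 2.64% for 168 other X-linked genes, 14.9% for 16 reported escape genes and 4.91% for 36 TE subfamilies.

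The second question, named in the series text, was how the allelic ratio of X-linked TE changed over the same days. X-linked TE drew 46.8% ± 0.154 of their allelic reads from the mus X at Day 0, 37.9% ± 0.145 at Day 2, 17.7% ± 0.785 at Day 4 and 5.14% ± 0.326 at Day 10. All 4 TE classes had low shares at Day 10. LINE elements were then at 4.74% ± 0.0484, SINE elements at 5.33% ± 0.436, LTR elements at 5.64% ± 0.814 and DNA transposons at 3.43% ± 0.746. The lowest share at Day 10 was that of L2a, an old LINE, which fell from 52.5% ± 4.22 at Day 0 to 1.21% ± 0.570 (log2 change of the ratio -6.52 ± 0.41, adjusted p = 5.08e-56). B1_Mur2 followed at 2.13% ± 0.805, PB1D11 at 2.89% ± 0.109 and URR1A at 2.91% ± 1.99. The highest were MIRc, an old SINE, at 12.3% ± 3.67 (-2.72 ± 0.29, adjusted p = 1.55e-19), B1_Mm at 10.8% ± 0.622, ID4_ at 10.6% ± 1.63 and B1_Mus2 at 8.32% ± 1.19. B1_Mur2 is missing from the table of 1 Day 0 library, where its mus and cas reads were equal, and its Day 0 share in the position files was 49.0% ± 1.37.

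The mus share of X-linked TE fell with day (r = -0.949, rho = -0.994, n = 16, permutation p = 1e-05 for both, adjusted p = 2.71e-05), and r was -0.971 without Day 10. Each class gave a like trend, with r = -0.945 for LINE, -0.947 for SINE, -0.958 for LTR and -0.950 for DNA elements, rho = -0.994, -0.994, -0.982 and -0.988, and the same permutation p (adjusted p = 2.71e-05). Without Day 10 their r was -0.969, -0.970, -0.974 and -0.975. Against the other TE, no class had a trend that passed over all days. LINE elements gave r = -0.370 (permutation p = 0.159, adjusted p = 0.189), SINE elements 0.0674 (0.810, 0.810), LTR elements 0.422 (0.102, 0.130) and DNA elements -0.470 (0.0644, 0.0875). Their rho was -0.450 (adjusted p = 0.112), -0.0888 (0.750), 0.521 (0.0648) and -0.385 (0.169). Without Day 10, r was -0.605 (permutation p = 0.0200, not adjusted) for LINE, -0.0155 (0.958) for SINE, 0.510 (0.0623) for LTR and -0.367 (0.195) for DNA elements, so whether LINE elements fell further than other TE up to Day 8 was left open. Of 235 X-linked TE subfamilies, the ratio was lower than at Day 0 in 28 at Day 2, 92 at Day 3, 163 at Day 4 and 194 at Day 10. At Day 1 the ratio was lower in 3 subfamilies and higher in 3. TE of chromosome 13, the background, had a mus share of 48.7% ± 0.0727 at Day 0 and 49.5% ± 0.304 at Day 10. This small rise passed the test (r = 0.785, permutation p = 3.9e-04, adjusted p = 7.41e-04, rho = 0.752, permutation p = 0.00119, adjusted p = 0.00216, and r = 0.766 without Day 10). The share first fell, to 47.3% ± 0.112 at Day 1, and the 2 libraries of these days lay close together. The permutation p-values of this rise may thus be too small. Chromosome 13 genes passed by Pearson (r = 0.543, permutation p = 0.0306, adjusted p = 0.0447) but not by Spearman correlation (rho = 0.420, permutation p = 0.109, adjusted p = 0.138), and not without Day 10 (r = 0.325, permutation p = 0.259).

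Whether X-linked TE and X-linked genes lost the mus allele by the same amount had no stable answer. The logit of the TE share minus that of the gene share, each less its chromosome 13 value, was -0.0366 ± 0.0291 at Day 0, -0.0262 ± 0.0341 at Day 4 and -0.0498 ± 0.0266 at Day 10. The difference fell with day by Pearson correlation (r = -0.545, permutation p = 0.0280, adjusted p = 0.0443), and not after adjustment by Spearman correlation (rho = -0.515, permutation p = 0.0443, adjusted p = 0.0648), with r = -0.644 without Day 10. With the median of genes and of TE subfamilies in place of pooled reads the sign turned (r = 0.876, permutation p = 3e-05), since the median X-linked gene reached 2.53% and the median of 98 TE subfamilies 4.56% at Day 10. The Pearson trend also ended when Day 1 replicate 1 (r = -0.502), Day 8 replicate 1 (-0.486) or Day 8 replicate 2 (-0.485) was left out.

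A further comparison asked whether the X that stays active rose relative to the autosomes of the same allele. The autosomal cas reads come from a minority of the autosomes. In 182 autosomal 10 Mb windows the median gene had at least 98.67% mus reads, against 57 windows near 1:1, 11 near 1:2 and 2 others. X-linked cas gene reads rose 1.53-fold relative to autosomal cas gene reads between Day 0 and Day 10 (log2 change 0.62 ± 0.01), and X-linked cas TE reads rose 1.25-fold (0.33 ± 0.04). For these changes and those of chromosome 13, the SE comes from the 2 Day 0 and 2 Day 10 libraries alone. Genes gave r = 0.965 with day and rho = 0.994 (permutation p = 1e-05, adjusted p = 2.71e-05, r = 0.948 without Day 10). TE gave r = 0.823 (permutation p = 1.5e-04, adjusted p = 3.17e-04) and rho = 0.787 (permutation p = 5.9e-04, adjusted p = 0.00125), with r = 0.715 without Day 10. The cas reads of chromosome 13, measured the same way, had no trend that passed, and at Day 10 they were 1.02-fold (log2 change 0.03 ± 0.02) for genes and 1.07-fold (0.10 ± 0.02) for TE. They were not flat in between, since the log2 ratio of chromosome 13 gene cas reads was -3.17 ± 0.02 at Day 0, -2.96 ± 0.00 at Day 4 and -3.13 ± 0.01 at Day 10, and that of its TE -3.30 ± 0.02 at Day 0 and -3.14 ± 0.00 at Day 1. The size of the X rise up to Day 4 therefore depends on the reference, while against chromosome 13 cas reads r was 0.962 for genes and 0.858 for TE over all days. Genes of chromosome 13 gave r = -0.143 (permutation p = 0.592, adjusted p = 0.625) and rho = 0.136 (permutation p = 0.617, adjusted p = 0.651), and its TE r = -0.229 (permutation p = 0.399, adjusted p = 0.446) and rho = -0.166 (permutation p = 0.542, adjusted p = 0.606). The X share of all allelic reads at Day 10 was 0.812-fold that of Day 0 for genes and 0.676-fold for TE. It fell with day for genes (r = -0.789, permutation p = 4.4e-04, adjusted p = 7.6e-04, rho = -0.746, permutation p = 0.00125, adjusted p = 0.00216, r = -0.876 without Day 10). It also fell for TE (r = -0.844, permutation p = 9e-05, adjusted p = 2.14e-04, rho = -0.864, permutation p = 4e-05, adjusted p = 9.5e-05, r = -0.905 without Day 10). For TE the cas rise was not seen in the median subfamily (r = 0.355, permutation p = 0.179).

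The position of genes along the X was described in windows of 10 Mb. At Day 0 the window with most genes, 70 to 80 Mb with 122 genes, had a mus share of 48.9% ± 0.150, and it was at 16.3% ± 0.567 at Day 4 and 5.29% ± 0.841 at Day 10. At Day 10 the lowest shares of the 16 windows were 1.64% ± 0.0158 at 140 to 150 Mb and 2.09% ± 0.975 at 110 to 120 Mb. The window of Xist, 100 to 110 Mb, was at 7.26% ± 0.373, with Ogt, Jpx and Ftx in it. The window at 30 to 40 Mb, which holds Slc25a5, had the highest share at Day 4, 41.1% ± 0.0860, and 19.2% ± 1.27 when Slc25a5 alone was left out. At Day 10 it was at 5.27% ± 0.176 without that gene. The order of the windows was alike between the replicates of a day (rho across windows 0.932 at Day 0, 0.976 at Day 4 and 0.932 at Day 10), and windows are not independent replicates.

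**Figure D3:**
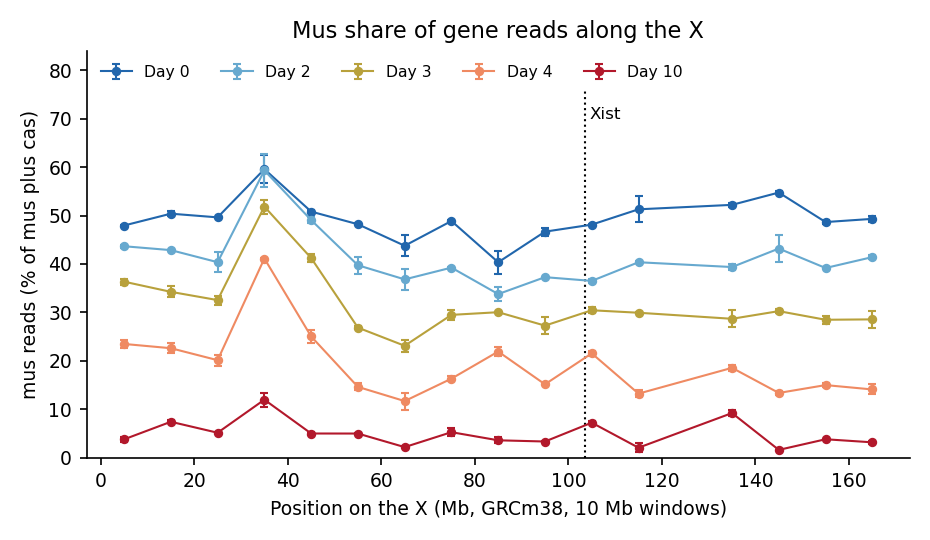
Mus share of X-linked gene reads (percent) in 10 Mb windows along the X chromosome (horizontal axis in Mb) at Days 0, 2, 3, 4 and 10, as means of 2 libraries with SD bars, with the place of Xist marked. The 30 to 40 Mb window stood at 59.6% at Day 0 and 41.1% at Day 4, and at 50.6% and 19.2% without Slc25a5.

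Gene expression was compared with Day 0 to describe the state of the cells in which these shares were measured, a comparison for which the series text states no question. At Day 2 the largest rises were those of Enpp2, which makes lysophosphatidic acid, Car4, a carbonic anhydrase, Fgf5, a growth factor of the postimplantation epiblast, and Slc23a1, a vitamin C transporter. Enpp2 rose from 0.0434 ± 0.0613 to 162 ± 31.0 CPM (adjusted p = 1.97e-07), a ratio of 3258 with a 95% counting interval of 901.5 to 26910 on 2 reads at Day 0. Car4 rose to 99.2 ± 7.18 CPM (ratio 1356, interval 463.6 to 6578), Fgf5 to 82.6 ± 4.41 CPM (1128, 385.5 to 5471) and Slc23a1 to 69.0 ± 8.13 CPM. All Day 0 reads of Enpp2 (2), Car4 (3) and Slc23a1 (4) lay in Day 0 replicate 2, so their size rests on that library, and the log2 changes were 10.77, 9.51 and 8.59 without Day 0 replicate 1. The largest falls were those of Crxos, a homeobox gene, from 62.5 ± 0.644 to 0.208 ± 0.0420 CPM (287.1-fold lower), and Sp5, a target of Wnt signalling, from 27.2 ± 7.11 to 0.125 ± 0.0924 CPM (log2 change -7.63, and -8.70 without Day 2 replicate 2). Mras, a small GTPase, fell from 141 ± 8.39 to 0.856 ± 0.538 CPM (-7.29, and -8.20 without Day 2 replicate 2), and Serpinb1a, a protease inhibitor, fell by a ratio of 181.9 (interval 61.95 to 884.7, and log2 change -8.07 without Day 2 replicate 1). Of 15731 genes tested, 4839 were higher and 4785 lower at Day 2, and at 2-fold or more 2473 were higher and 1858 lower.

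At Day 4 naive pluripotency genes had fallen and genes of the formative epiblast had risen. All 18 naive genes were lower (camera adjusted p = 2.17e-09, and adjusted p = 0.211 with an estimated correlation). Among these transcription factors of the ground state, Tfcp2l1 fell from 1677 ± 3.56 to 21.4 ± 2.48 CPM (log2 change -6.28 ± 0.11), Esrrb from 1089 ± 21.4 to 59.3 ± 16.8 (-4.19 ± 0.31) and Nanog from 1194 ± 48.1 to 206 ± 6.31 (-2.53 ± 0.16). Of 13 formative genes 11 were higher and 0 lower (camera adjusted p = 3.47e-07, and adjusted p = 0.211 with an estimated correlation). The DNA methyltransferase Dnmt3b rose from 116 ± 6.16 to 2331 ± 84.8 CPM (4.33 ± 0.16), Dnmt3a from 86.0 ± 0.537 to 494 ± 20.4 (2.52 ± 0.12) and the transcription factor Pou3f1 from 8.14 ± 0.505 to 350.6 ± 6.14 (5.42 ± 0.18). Of 26 imprinted genes 18 were higher and 4 lower, or 19 and 4 adjusted over the list alone (camera adjusted p = 1.18e-04, and adjusted p = 0.211 with an estimated correlation). Peg3 rose from 60.9 ± 6.22 to 281 ± 7.20 CPM (2.21 ± 0.13) and Peg10 from 229 ± 10.5 to 416 ± 18.4 (0.86 ± 0.08). Of 22 Hox genes 15 were lower and 0 higher (camera adjusted p = 0.00145, and adjusted p = 0.211 with an estimated correlation). Hoxd9 fell from 8.95 ± 0.216 to 0.140 ± 0.132 CPM (-6.04 ± 0.34). Of 30 X-linked housekeeping genes 22 were lower and 3 higher (camera adjusted p = 5.78e-05, and adjusted p = 0.235 with an estimated correlation). Uba1, the ubiquitin-activating enzyme, fell from 1290 ± 34.3 to 595 ± 6.03 CPM (-1.12 ± 0.05). Flna, an actin-binding protein, was at 1569 ± 5.39 and 1518 ± 26.5 CPM (adjusted p = 0.506). Members that went the other way, named after their values were seen, were the imprinted genes Plagl1, Grb10, Igf2r and Phlda2 and the X-linked genes Stag2, Phf6 and Rlim, an activator of Xist.

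The largest rises at Day 4 were those of Fgf5, to 229.5 ± 1.11 CPM (ratio 3119, 95% counting interval 1067 to 15130), and Enpp2, to 141 ± 4.53 CPM (2888, 799.2 to 23860). Gabra3, a GABA receptor subunit, was at least 83.32-fold higher at 12.5 ± 1.04 CPM, and Car14, another carbonic anhydrase, was at 121 ± 11.3 CPM. All Day 0 reads of Enpp2 (2) and Car14 (4) lay in Day 0 replicate 2, and the log2 changes were 10.55 and 9.38 without Day 0 replicate 1. The largest falls were those of Serpinb1a (at least 92.27-fold lower), Crxos (ratio 1209, interval 334.3 to 9986), Xpnpep2, an aminopeptidase (733.2, 131.2 to 29000), and Pkd2l1, a cation channel (572.1, 158.0 to 4730). The only Day 4 read of Xpnpep2 lay in Day 4 replicate 2, and its log2 change was -8.48 without Day 4 replicate 1. In all, 5180 genes were higher and 5302 lower at Day 4, and at 2-fold or more 2650 were higher and 2430 lower. Core pluripotency genes were not called as a list at Day 4, with 4 of 13 higher and 5 lower, and Pou5f1 was at 544 ± 7.02 CPM at Day 0 and 540.5 ± 13.2 at Day 4 (log2 change -0.01 ± 0.24, adjusted p = 0.978).

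**Figure D4:**
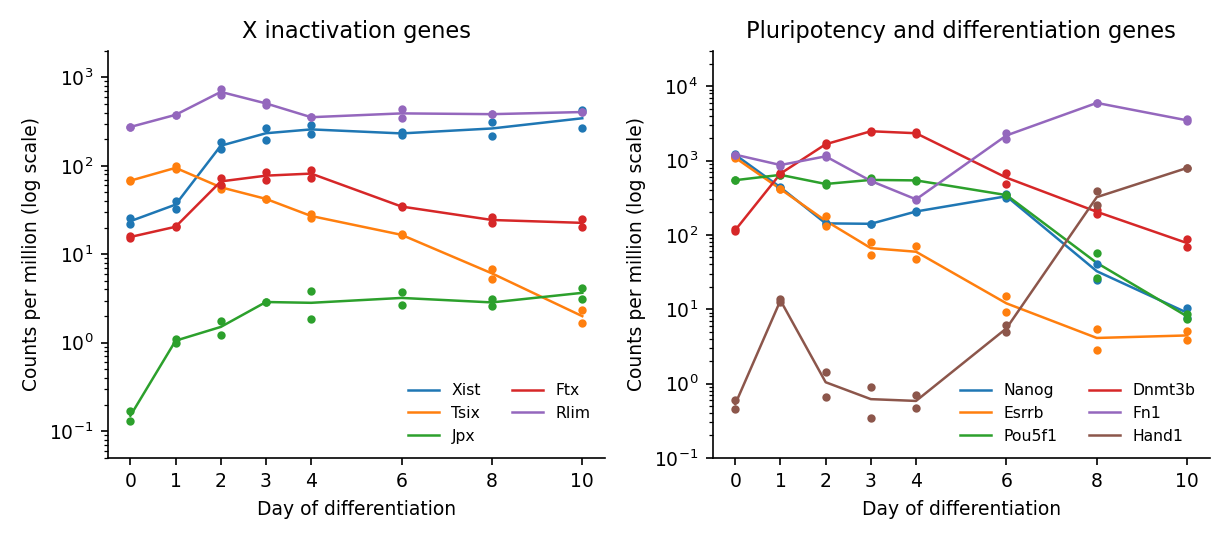
Expression in CPM (log axis) by day of differentiation for genes of X inactivation (left) and of pluripotency and differentiation (right), with 1 point per library and lines through the means of 2 libraries. Xist went from 23.7 to 345 CPM and Tsix from 68.0 to 2.00 CPM between Day 0 and Day 10, and Dnmt3b was at 2331 CPM at Day 4 and 77.5 at Day 10.

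At Day 10 the cells expressed genes of mesenchyme, extracellular matrix and mesoderm that were near the floor at Day 0. Acta2, smooth muscle actin (chromosome 19, 34240336 to 34255585), rose from 0.282 ± 0.399 to 1626 ± 291 CPM (adjusted p = 2.58e-08). Cdh11, a mesenchymal cadherin (chromosome 8, 102632095 to 102785493), rose to 746 ± 23.8 CPM (log2 change 12.50, adjusted p = 7.77e-15, and 13.52 without Day 0 replicate 2). Postn, a matrix protein (chromosome 3, 54359267 to 54391041), rose to 646 ± 78.9 CPM (ratio 8780, 95% counting interval 3004 to 42580). All Day 0 reads of Acta2 (13) and Postn (3) lay in Day 0 replicate 2, so their size rests on that library, and the log2 changes were 11.47 and 12.21 without Day 0 replicate 1. Unc5c, a netrin receptor without a read at Day 0, was at least 1543-fold higher at 231 ± 20.8 CPM (adjusted p = 1.41e-11). Also without a read at Day 0 were Rbms3, an RNA-binding protein (at least 946.1-fold), Svep1, an adhesion protein (at least 894.7-fold), and Megf10, an engulfment receptor (at least 829.5-fold). The same held for Col4a6, a basement membrane collagen (at least 640.2-fold), Twist2, a mesenchymal transcription factor (at least 459.8-fold), and Hoxb6 (at least 193.3-fold). The 10 largest falls included Crxos (ratio 2284, interval 409.6 to 90260) and the glycosyltransferase gene B3gnt3 (1927, 345.5 to 76160). Their only Day 10 read lay in Day 10 replicate 1, so their size rests on that library, and the log2 changes were -9.99 and -9.74 without Day 10 replicate 2. The other 8 had no read at Day 10. Fetub was at least 338.2-fold lower, from 55.6 ± 1.54 CPM, Nkx6-2, a homeobox gene, at least 195.5-fold, Arl14epl at least 171.4-fold and Cd4 at least 142.7-fold. They were followed by Krtdap (at least 119.5-fold), Syce1, of the meiotic synaptonemal complex (at least 116.7-fold), Calb2, a calcium-binding protein (at least 114.4-fold), and Lrrc2 (at least 94.77-fold). In all, 6077 genes were higher and 6183 lower at Day 10, and at 2-fold or more 3690 were higher and 3401 lower.

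The lists that rose at Day 10 were those of extracellular matrix, fibroblasts, mesoderm, endoderm, Hox genes and imprinted genes. Of 20 genes of extracellular matrix and adhesion 19 were higher and 0 lower (camera adjusted p = 8.32e-09, and adjusted p = 0.106 with an estimated correlation). Fn1, fibronectin, rose from 1199 ± 2.04 to 3472 ± 159 CPM (log2 change 1.53 ± 0.07) and Col4a1 from 113 ± 7.19 to 1098 ± 22.7 (3.28 ± 0.09), while the laminin gene Lamc1 was at 800.3 ± 11.2 and 795 ± 46.5. Of 16 fibroblast and feeder genes 14 were higher and 2 lower (camera adjusted p = 6.66e-05, and adjusted p = 0.133 with an estimated correlation). Vim, an intermediate filament gene, rose from 149 ± 24.7 to 2145 ± 180 CPM (3.85 ± 0.13) and Col1a1 from 2.97 ± 1.25 to 1952 ± 86.5 (9.31 ± 0.35). Fn1, Vim, Col1a1 and Acta2 of this list are expressed by mesenchymal cells in general. Of 19 primitive streak and mesoderm genes 15 were higher and 1 lower (camera adjusted p = 6.66e-05, and adjusted p = 0.146 with an estimated correlation). Hand1 rose from 0.529 ± 0.110 to 795 ± 9.60 CPM (10.51 ± 0.32) and Eomes from 9.94 ± 0.415 to 25.7 ± 11.1 (1.37 ± 0.26), while T was at 3.93 ± 1.49 and 8.56 ± 4.14 (adjusted p = 0.136). Of 16 genes of primitive and parietal endoderm 11 were higher and 4 lower (camera adjusted p = 0.00698, and adjusted p = 0.146 with an estimated correlation). Sparc, which like Col4a1 is also a matrix gene, rose from 344 ± 15.8 to 1469 ± 161 CPM. Of 22 Hox genes 16 were higher and 1 lower (camera adjusted p = 0.00594, and adjusted p = 0.146 with an estimated correlation). Hoxb2 rose from 0.108 ± 0.153 to 38.1 ± 1.78 CPM (8.21 ± 0.34). Of 26 imprinted genes 23 were higher and 2 lower (camera adjusted p = 5.37e-08, and adjusted p = 0.0263 with an estimated correlation). Peg3 rose to 5065 ± 239 CPM (6.38 ± 0.16), Mest from 157 ± 6.75 to 2489 ± 103 (3.99 ± 0.14) and H19, a noncoding RNA, from 17.9 ± 2.86 to 4099 ± 280 (7.83 ± 0.29). Members of these lists that were lower, named after their values were seen, were Thy1 and Timp1 (fibroblast), Gsc (streak), Srgn, Amn, Sox7 and Apoe (endoderm), Hoxa7, and Grb10 and Phlda2 (imprinted).

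The lists that fell at Day 10 were those of pluripotency, germ cells, the cell cycle, TE silencing and X-linked housekeeping genes. All 18 naive genes were lower (camera adjusted p = 9.47e-09, and adjusted p = 0.146 with an estimated correlation). Tfcp2l1 fell to 3.67 ± 0.741 CPM (log2 change -8.83 ± 0.14) and Nanog to 8.95 ± 2.05 (-7.06 ± 0.21). Of 13 core pluripotency genes 12 were lower and 1 higher (camera adjusted p = 6.66e-05, and adjusted p = 0.195 with an estimated correlation). Pou5f1 fell to 7.99 ± 0.934 CPM (-6.09 ± 0.33), and the higher one was Lin28a, an RNA-binding protein that blocks let-7, at 113 ± 24.9 and 501 ± 9.67 (2.14 ± 0.10). Of 15 germ cell genes 14 were lower, or 15 adjusted over the list alone, and 0 higher (camera adjusted p = 4.36e-05, and adjusted p = 0.0263 with an estimated correlation). Tex19.1, which restrains TE in the germline, fell from 99.0 ± 6.42 to 0.273 ± 0.230 CPM (-8.46 ± 0.23). Of 22 cell cycle genes 20 were lower and 1 higher (camera adjusted p = 8.05e-06, and adjusted p = 0.146 with an estimated correlation). Mcm2, of the replicative helicase, fell from 866 ± 10.8 to 399 ± 5.14 CPM (-1.12 ± 0.05) and Top2a from 791 ± 15.9 to 502 ± 49.2 (-0.66 ± 0.06). Of 26 genes of TE silencing 21 were lower and 3 higher (camera adjusted p = 2.69e-04, and adjusted p = 0.146 with an estimated correlation). Rif1 fell from 864 ± 19.5 to 226 ± 18.8 CPM (-1.94 ± 0.09) and the corepressor Trim28 by 0.66 ± 0.05 on the log2 scale. Of 30 X-linked housekeeping genes 19 were lower and 8 higher (camera adjusted p = 0.0194, and adjusted p = 0.413 with an estimated correlation). The ribosomal protein gene Rps4x fell from 1014 ± 59.7 to 536 ± 15.1 CPM (-0.92 ± 0.06), and Flna rose to 4106 ± 335 (1.39 ± 0.06). Higher members, named after their values were seen, were Ccne2 of the cell cycle list and Dnmt3a, Pphln1 and Chaf1a of the TE silencing list. Among immediate early and stress genes, a sign of RNA quality, 7 of 14 were higher and 4 lower at Day 10 (camera adjusted p = 0.766). The heat shock genes Hspa8 and Hsp90aa1 fell by 0.46 ± 0.06 and 0.99 ± 0.06 on the log2 scale and Jun rose by 3.53 ± 0.18.

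The last comparison asked which TE subfamilies changed in their allele-assigned reads, summed over all chromosomes and both alleles. TE reads that could not be assigned to an allele are not in these counts. Reads of a TE that lies inside a gene were not separated from reads of that gene. Among the subfamilies that changed by Day 10, most LTR elements were lower and most DNA transposons were higher. Of 484 LTR subfamilies 35 were higher and 145 lower, and of 186 DNA subfamilies 42 were higher and 9 lower. Of 166 LINE subfamilies 41 were higher and 15 lower, and of 38 SINE subfamilies 10 were higher and 1, B2_Mm1a, lower. The largest rise was that of ERVB4_1-I_MM, the internal part of an endogenous retrovirus, from 5.38 ± 0.157 to 1113 ± 207 CPM in the position files (log2 change 7.65 ± 0.19, adjusted p = 2.67e-25). ETnERV3-int rose from 5.77 ± 0.712 to 67.1 ± 16.8 CPM (3.47 ± 0.40). The DNA elements Eulor5A, MER135, UCON73 and X9a_DNA rose by log2 changes of 2.59 ± 0.43, 2.20 ± 0.39, 2.17 ± 0.38 and 1.39 ± 0.40. Among LTR elements, MERV1_LTR fell from 81.6 ± 18.8 to 19.2 ± 1.12 CPM (-2.05 ± 0.27) and ERVB4_1B-I_MM from 40.4 ± 0.526 to 8.30 ± 5.01 (-2.36 ± 0.35). ERVB3_1-I_MM fell from 37.7 ± 1.10 to 4.06 ± 1.70 CPM (-3.24 ± 0.48), and RLTR13B2 had a log2 change of -2.18 ± 0.36. MER34-int had 109 reads at Day 0 and 4 at Day 10 (47.6 ± 13.7 and 2.27 ± 0.514 CPM), and ERVB3_1-LTR_MM 106 and 2 (45.6 ± 19.8 and 1.32 ± 1.86 CPM). The 6 highest and 6 lowest were picked on counts that left out values under 5 reads and ties. In those counts all but ERVB4_1-I_MM stood at 0 on 1 of the 2 days. Their log2 changes were then larger, such as 6.97 for X9a_DNA and -9.12 for MERV1_LTR. They are thus not all the most extreme subfamilies, and ETnERV2-int fell further than MERV1_LTR.

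Among the TE lists, 7 of 15 RLTR9 and RLTR13 subfamilies were lower at Day 10 and 0 higher (camera adjusted p = 0.0134, and adjusted p = 0.115 with an estimated correlation). RLTR9E, whose copies carry binding sites of pluripotency factors, fell from 912 ± 54.2 to 86.6 ± 13.8 CPM (log2 change -3.38 ± 0.18) and RLTR9D from 361 ± 16.6 to 81.4 ± 23.9 (-2.18 ± 0.18). Of 18 MaLR subfamilies 9 were lower and 1 higher at Day 10, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.595 with an estimated correlation). ORR1B1 was at 2291 ± 112 and 1936 ± 14.4 CPM (-0.24 ± 0.08), and its call was lost with factors from the gene table (adjusted p = 0.138). The largest falls of the list, named after their values were seen, were those of ORR1A0-int (-1.22 ± 0.14) and ORR1A0 (-0.85 ± 0.17), which were called with both kinds of factors. At Day 4, 4 MaLR subfamilies were lower and 0 higher (camera adjusted p = 0.0455, and adjusted p = 0.781 with an estimated correlation). ETnERV2-int fell from 306 ± 15.3 to 13.7 ± 1.62 CPM at Day 10 (-4.49 ± 0.27). MMETn-int was higher at Day 4 (200.3 ± 23.2 to 508 ± 97.7 CPM, 1.34 ± 0.17) and lower at Day 10 (40.9 ± 0.721, -2.29 ± 0.22).

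Of 882 TE subfamilies tested, 63 were higher and 88 lower at Day 4, and 130 higher and 170 lower at Day 10. Library sizes from the gene table moved the median log2 change at Day 10 from 0.00 to -0.13. With these, 19 were higher and 58 lower at Day 4, and 55 higher and 141 lower at Day 10. By class, higher and lower at Day 10 were then 18 and 121 of the LTR, 20 and 7 of the DNA, 13 and 12 of the LINE and 3 and 1 of the SINE subfamilies. In the position files they were 53 and 177 of 517 LTR, 81 and 11 of 208 DNA, 52 and 22 of 175 LINE and 12 and 2 of 38 SINE subfamilies. The Day 4 count of 151 was 87, 81, 86 and 104 without Day 0 replicate 1, Day 0 replicate 2, Day 4 replicate 1 and Day 4 replicate 2, where fewer libraries were tested, and 251 in the position files. In the tables, the calls of UCON73, MER135 and X9a_DNA were lost without Day 0 replicate 1 (adjusted p = 0.0768, 0.0768 and 0.0876) or 2 (0.0913, 0.0944 and 0.110), and for MER135 and X9a_DNA without Day 10 replicate 2 (0.0518 and 0.0532). Those of ERVB3_1-I_MM and ERVB3_1-LTR_MM were lost without Day 10 replicate 1 (0.0596 and 0.110) or 2 (0.0601 and 0.104), and of the latter without Day 0 replicate 2 (0.192).

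**Figure D5:**
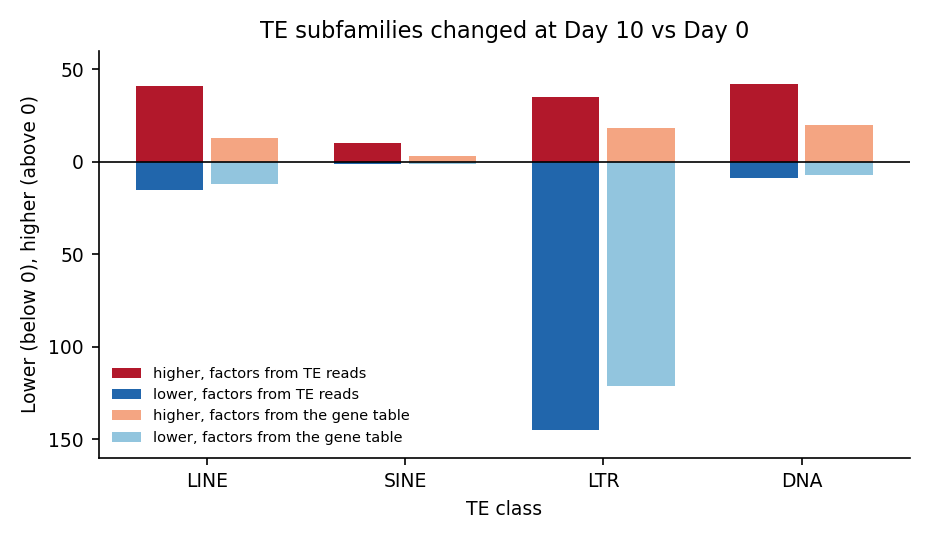
Number of TE subfamilies of each class (horizontal axis) that were higher (bars above 0) or lower (bars below 0) at Day 10 than at Day 0, with library factors from TE reads (dark) or from the gene table (light). With factors from TE reads, 145 LTR subfamilies were lower and 35 higher and 41 LINE subfamilies higher and 15 lower, and with those from the gene table LINE subfamilies were 13 higher and 12 lower.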

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

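The test of a general preference of the allele assignment for cas was chosen only after the chromosome 8 shares had been seen.

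Many genes went opposite ways at Day 4 and Day 10, each against Day 0 with an adjusted p under 0.05 in edgeR: 864 genes were higher at Day 4 and lower at Day 10, and 924 were lower at Day 4 and higher at Day 10. Both changes share the Day 0 libraries, and the contrast of Day 10 with Day 4 tested the difference itself and called 11557 genes and 184 TE subfamilies. Dnmt3b and Pou3f1, of the formative epiblast, were higher at Day 4 and lower at Day 10, with Dnmt3b at 116 ± 6.16, 2331 ± 84.8 and 77.5 ± 13.2 CPM on Days 0, 4 and 10 (SD, n = 2). Fn1 and Sparc were lower at Day 4 and higher at Day 10, with Fn1 at 1199 ± 2.04, 300.5 ± 10.6 and 3472 ± 159 CPM. Among TE subfamilies, named after their values were seen, 6 were higher at Day 4 and lower at Day 10 and 3 the other way, but with library factors from the gene table only MMETn-int, RLTR9A and ERVB7_3-LTR_MM kept both calls, while RLTR13G lost the one at Day 4 (adjusted p = 0.118) and MER91B and RLTR21 the one at Day 10 (0.223 and 0.141).

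Of 22 Hox genes, which pattern the body axis, 15 were lower at Day 4 than at Day 0 (camera adjusted p = 0.00145, and adjusted p = 0.211 with an estimated correlation), and 21 were higher at Day 10 than at Day 4 (camera adjusted p = 4.54e-07, and adjusted p = 0.057 with an estimated correlation). Hoxd9 went from 8.95 ± 0.216 to 0.140 ± 0.132 and 9.07 ± 0.199 CPM on Days 0, 4 and 10.

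A part of chromosome 8, whose allelic shares were not compared, had a mus share near 1 of 3, and its reads are among the autosomal cas reads and the TE totals. In its first 70 Mb, the median of 173 genes was 32.8% ± 0.248 mus at Day 0 and 32.9% at Day 10, while the 4 heterozygous windows of chromosome 6 stood at 27.99 to 35.6%. An allele assignment that prefers cas in general would have lowered other heterozygous windows too, and the median of all 62 outside chromosome 8, whatever their share, was 50.2%. Regulation that follows differentiation would have moved the share, which changed by 0.0870 percentage points from Day 0 to Day 10. An extra cas copy of the segment may be a candidate explanation, but no DNA data were used here. TE reads in the first 70 Mb of chromosome 8 were at 34.8% mus on average over 16 libraries (33.7 to 35.4% per library). Each allele was counted in the coordinates of its own genome, so the mus, cas and gene segments need not be the same. The TE share is thus weak evidence, and an assignment or strain difference confined to such segments was not tested.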

How the results depend on the processing

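Tests on TE counts from the position files, with identical coordinates counted once, and on shares without genes of biased Day 0 share or without the escape list were chosen after the data had been seen. Of 253 alternatives to 24 results that answer a comparison, 222 gave the same result, 22 moved it, 6 weakened it and 3 reversed its sign. A count within 1.5-fold of the main one was scored as the same, so the same result does not mean an equal count. For TE subfamilies at Day 10 the main count of 300 was scored as the same at 416 with reads counted from the position files. Of 682 alternatives for 70 genes and TE subfamilies named by the rule, 660 gave the same result, 22 ended a call and 0 reversed one, and of 2907 for list examples 109 ended a call, 39 added one and 0 reversed one. A 2-fold minimum left 4331, 5080 and 7091 genes at Days 2, 4 and 10, and 77 and 152 TE subfamilies at Days 4 and 10, by its construction. Leave-one-out gave 81 to 104 TE subfamilies at Day 4 against 151 with all libraries (87 and 81 without Day 0 replicate 1 and 2, and 86 without Day 4 replicate 1), where the lone library of a day is assumed to vary like the others. Factors from the gene table gave 77 TE subfamilies at Day 4 and 196 at Day 10. The position files gave 251 at Day 4, and 259 with identical coordinates counted once. A minimum of 50 allelic reads left 102 X-linked TE subfamilies to test, of which 94 and 98 had a lower mus share at Days 4 and 10. With an estimated correlation, 0 gene lists of 5 were called at Day 4 and 2 of 12 at Day 10 (germ cell and imprinted genes), and 0 TE lists on both days. The trend of the TE minus gene share was r = -0.545, and it was -0.637 to -0.485 with 1 library left out (p = 0.0556 without Day 1 replicate 1, 0.0647 and 0.0683 without Day 8 replicate 1 and 2), -0.211 without the autosomal correction and -0.0331 without the 5 items with most reads. Its sign turned, to 0.876 with the median of items, 0.134 without genes of Day 0 share outside 30 to 70% and 0.356 without the escape list, and the cause was not tested. The last 2 values are weak, and they end the trend without showing one the other way. The cas X trend of TE was r = 0.355 with the median of items, and the cause was not tested. The mus share at Day 10 was 2.53% for genes and 4.56% for TE with the median of items, and 5.25% and 5.13% for genes without those of biased Day 0 share and without the escape list. With a replicate block the permutation p of the TE minus gene trend was 0.0346 and 6 gene lists were called at Day 4, with the cell cycle added (adjusted p = 0.0493), the ratio of Ngfrap1 lost its call (adjusted p = 0.0531), and the other results that answer a comparison kept theirs. Replicate numbers did not meet the rule for pairing, which needs every correlation of deviations between days over 0.1: 18 of 28 were, with a median of 0.172 and a range of -0.0727 to 0.577. Replicate 1 had the higher chromosome 13 gene mus share on 8 of 8 days and the higher chromosome 13 TE share on 4, and the higher share of distinct TE read coordinates on 8 of 8, so a difference that goes with the number is not excluded. Of the named items 8 lost a call at Day 10 under some alternative, and in 7 of them the change kept its sign. MER34-int (adjusted p = 0.341) and ERVB3_1-LTR_MM (0.386) lost it with DESeq2. UCON73, MER135, X9a_DNA, ERVB3_1-I_MM and ERVB3_1-LTR_MM lost it with 1 library left out (adjusted p = 0.0518 to 0.192), as did the mus to cas ratio of Ngfrap1 (0.332 without Day 0 replicate 1) and of B1_Mur2, which has no Day 0 value without replicate 1 because tied entries are absent from the tables. The planned TE windows from the position files were not run. Recovery in simulated data was lowest for X-linked TE, the set with the fewest reads, with 14 of 20 2-fold changes of their mus share recovered against 40 of 41 for X-linked genes, and depth itself was not varied.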

Other observations

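The tests of distance from Xist, and the shares of imprinted genes, were chosen only after the shares by window had been seen.

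Several other gene groups changed in part, without a call of the list by camera on either day. DNA demethylation genes split, with 5 of 7 lower and 2 higher on both days. Tet1 went from 1182 ± 3.38 to 455 ± 37.5 and 111 ± 24.7 CPM on Days 0, 4 and 10 and Tet2 from 590 ± 6.89 to 16.4 ± 0.512 and 39.0 ± 6.66, while Tet3 rose from 63.4 ± 0.360 to 116 ± 8.59 and 279.7 ± 12.6 (SD, n = 2). Of 11 definitive endoderm genes 5 were higher and 2 lower at Day 4, and 7 higher and 3 lower at Day 10, when Gata6 had a log2 change of 7.72 ± 0.21. Of 12 trophectoderm genes 2 were higher and 6 lower at Day 4, and 6 higher and 5 lower at Day 10, with Krt8 and Krt18, keratins of simple epithelia, higher by log2 changes of 3.74 ± 0.10 and 5.63 ± 0.11 at Day 10 and Tfap2c lower by a log2 change of -4.04 ± 0.17. Of 14 neurectoderm genes 7 were higher and 4 lower at Day 4, and 5 higher and 6 lower at Day 10, when Sox11 was higher by 6.45 ± 0.09. Of 9 endothelial and blood genes 2 were higher and 4 lower at Day 4, and 5 higher and 3 lower at Day 10, when Runx1 was higher by 5.38 ± 0.19. Of 12 cardiac and muscle genes 4 were higher and 3 lower at Day 4, and 7 higher and 4 lower at Day 10, with Ryr2 higher by 1.65 ± 0.23. Of 16 genes of interferon and double-stranded RNA sensing 5 were higher and 8 lower at Day 4, and 7 higher and 6 lower at Day 10, with Mavs, the adaptor of RNA sensors, lower by -2.64 ± 0.08 on the log2 scale. Of 14 genes of cell cycle arrest and the p53 response 5 were higher and 7 lower at Day 4, and 8 higher and 5 lower at Day 10, with Ccng1 higher by 1.07 ± 0.10.

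Of 23 Polycomb and heterochromatin genes 9 were higher and 10 lower at Day 4, and 7 higher and 13 lower at Day 10, with Jarid2 lower by -1.12 ± 0.08 on the log2 scale and Cbx5 higher by 0.59 ± 0.14. Of 23 regulators of X inactivation 12 were higher and 7 lower at Day 4, and 10 higher and 10 lower at Day 10, with Rlim higher by 0.56 ± 0.08 and Smchd1, needed to keep the X silent, by 0.59 ± 0.09. Of 23 reported escape genes 6 were higher and 8 lower in total expression at Day 4, and 10 and 10 at Day 10. Of 9 genes of the 2-cell-like state 0 passed at Day 4 and 1 was lower at Day 10, Zscan4d, and 0 adjusted over the list alone, and all 9 means stayed under 1 CPM on these days. At Day 4, 1 of 14 immediate early and stress genes was higher (Jun, named after its value was seen) and 8 lower, 0 of 22 cell cycle genes were higher and 13 lower, 7 of 20 matrix genes higher and 6 lower, 4 of 16 fibroblast genes higher and 3 lower, 4 of 15 germ cell genes higher and 9 lower, 5 of 16 endoderm genes higher and 6 lower, 4 of 19 streak genes higher and 8 lower, and 6 of 26 TE silencing genes higher and 10 lower. At Day 10, 7 of 13 formative genes were higher and 5 lower. The median, the mean and the direction of the camera test differed in sign for lists without a call, such as core pluripotency and Polycomb genes at Day 4 and interferon genes at Day 10. Among TE lists without a call, counts higher and lower at Day 10 were 2 and 0 of 15 B1, 0 and 1 of 5 B2, 1 and 0 of 7 B4, 0 and 2 of 7 ERVK10C, 1 and 3 of 5 ETn and MusD, 2 and 3 of 11 IAP, 0 and 2 of 8 MERVL, and 1 and 1 of 7 VL30 and MuLV subfamilies. Under the names listed, the tables hold 0 of 15 mitochondrial genes, 0 of 5 satellites and 0 of 7 young L1 subfamilies. Young L1 elements are in the tables under finer names, such as L1MdA_I and L1MdTf_III, and were counted among the LINE subfamilies but not tested as a list.

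Imprinted genes in heterozygous parts of the genome had reads from both alleles. Peg10, which was at 10462 ± 821 CPM at Day 10, had a mus share of 33.1% ± 1.83 at Day 0 and 34.8% ± 0.123 at Day 10 on 139077 allelic reads, in a window of chromosome 6 with a median of 27.99%. Its neighbour Sgce was at 39.1% ± 2.58 and 32.7% ± 2.68. At Day 10 Ndn was at 46.3% ± 4.83 on 320 reads and Magel2 at 68.3% ± 5.79 on 100 reads, in a window of chromosome 7 with a median of 51.7%, and Gnas was at 60.8% ± 0.813 on 222 reads. No cause of these shares was tested.

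Whether X-linked genes near Xist lost the mus allele earlier was not settled. At Day 2 the median log2 change of the mus to cas ratio was -0.57 in 87 genes within 30 Mb of Xist and -0.32 in 67 genes beyond 60 Mb, and across 270 genes, which are not independent replicates, distance and change had rho = 0.290. A permutation test that rotated the gene order 270 ways gave values as large (permutation p = 0.356, adjusted p = 0.741), so distance from Xist cannot be told apart from a chance arrangement of genes. Day 2 had the largest rho, against 0.155 at Day 1, 0.200 at Day 3 and 0.0630 to 0.0748 from Day 4 on, when most of the mus allele was lost. The Day 2 value was 0.300 with genes ranked within quartiles of their reads and 0.307 without the reported escape genes, so neither step lowered it. At most 22 of the 270 genes could be on the escape list, so leaving them out could move rho little. Since rho itself was not told apart from chance, no conclusion is drawn from these 2 values.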
